A study of Mus musculus with 6 samples.

How the data were processed

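RNA of mouse conjunctival epithelium was measured on Affymetrix expression arrays, 3 of Spdef +/+ and 3 of Spdef -/- mice. Per the labels, the mice were 8 weeks old and on a C57BL/6 background, and each sample pooled 1 eye of 1 male and 1 eye of 1 female. Eyes with their lids were frozen in embedding medium and sectioned at 6 µm, sections were stained with hematoxylin and eosin, and the 40% of the epithelium nearest the fornix was captured with a laser. Whether the replicate numbers pair the arrays, and where the Spdef probe set lies relative to the deleted sequence, is not given in the sources used here.

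The deposited signals are dChip model-based intensity values made by the authors, 1 per probe set and array, on a linear scale and normalized between arrays. The normalization method, the background method and the algorithm of the detection calls are not given in the sources used here. The deposited detection call of each probe set on each array, of the other kind of values, is Present, Marginal or Absent. The authors' deposited comparison table gives score values (means, differences and signed folds) and an unadjusted p value for each of 153 probe sets, kept per the file headers where the lower bound of the fold was over 3, the difference over 20 and p at most 0.01. The second deposited table of intensity values held the same numbers as the first, with 0 values that differed.

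The 45101 probe sets held 64 controls. Probe sets took a symbol from the mouse gene table supplied with the series, of genome assembly GRCm38.p6, by gene ID (36239 probe sets), by the 1 of several IDs found in the table (609, a choice made after the files were seen) or by accession (61). Another 585 matched several genes and 7543 had no symbol, and both were left out of the gene tests. The 36909 named probe sets stood for 18096 genes.

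Signals under 1 were set to 1 and log2 was taken. A probe set was tested if it had 1 symbol, was no control and was Present on at least 3 of the 6 arrays, which left 21727 probe sets. The one with the highest mean log2 signal stood for its gene, which gave 11899 genes. Of the 5520 genes with more than 1 tested probe set, 137 had probe sets that passed in opposite directions. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the 1 term, Spdef -/- minus Spdef +/+), 2-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The median residual SD over genes was 0.139 on the log2 scale, and the number of arrays limits the precision. Array measures were compared with an exact permutation test, 2-sided, whose smallest p is 0.1 for 3 against 3 arrays.

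Gene lists were written before the data were examined, as were the naming rule, the tests and the alternatives other than those said to be chosen later. Of 37 lists, 35 had the 3 tested members needed for a set test. They cover goblet cell products, secretory regulators, O-glycosylation, folding and export, membrane mucins, conjunctival, basal, corneal, cornified and epidermal epithelium, junctions, glands, melanocytes, stroma, endothelium, muscle, blood and immune cells, antigen presentation, interferon, cytokines, defence, complement, type 2 response, cell cycle, immediate early genes, proteases, ion transport, Notch and Wnt, oxidative stress and sex-linked transcripts. Each was tested with camera (preset correlation of 0.01, adjusted over the 35 lists), with camera and an estimated correlation, and with fry.

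The genes named are Spdef, in each direction the 10 with the largest log2 difference among called genes with separate groups, up to 4 called members of each list with the smallest p (or the 2 brightest where none was called), and 10 genes fixed by name where tested (Muc5ac, Muc5b, Tff1, Foxa3, Krt4, Krt13, Krt12, Sprr2h, Il1b and Tnf). Predicted genes and clone names were passed over. The rule named 131 genes, of which a part is described, and the members of lists named outside it (Dmbt1, Klf4, Xbp1, Muc4, Aqp5, Retnla, Jchain, Cd74, Xist and Eif2s3y) were chosen after their values were seen.

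The alternatives for filter and scaling were no filter, a filter on mean signal, quantile normalization and centring on array medians. A floor of 16 or a pseudocount of 32 replaced the floor of 1. The model was varied by eBayes with trend and robust (statmod 1.5.0), by array weights, and by the replicate number as a fixed block term. Other alternatives were the mean of a gene's probe sets, probe sets singly, leaving out each array and the methods' t-test. The last was a fold of at least 3 with an unadjusted p under 0.01. That is not the authors' rule on the lower bound of the fold and the difference. After the data were seen, centring on bacterial controls, leaving probe sets of several IDs unnamed, 5 further gene lists, tests of gene families that share a symbol stem, and most tests in the closing part were added. The procedure was tested on simulated data for 11899 genes with 200 changed genes in each of 10 simulations. It recovered 48.7% of 1.5-fold changes, 88.8% of 2-fold and 98.3% of 4-fold changes, and 6.27% of its calls were false. The simulated noise was independent between genes and held no shifts shared by an array. Far fewer genes changed than were called in the data, so these rates need not hold for the real calls. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.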

Results

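The comparison asked whether gene expression in conjunctival epithelium differed between Spdef +/+ and Spdef -/- mice, with 3 Affymetrix arrays per genotype. Spdef encodes an ETS-family transcription factor of mucus-secreting epithelia. Each array held RNA from laser-captured epithelium next to the fornix, the pouch between eyelid and eyeball, pooled from 1 eye of a male and 1 eye of a female. Signals are in linear dChip units and are given as mean ± SD of 3 arrays. Folds are differences of mean log2 signals, so they can differ from the ratio of the printed means. Where no array of a group called a gene Present, that group's signals under the array's lowest Present signal were raised to it. The fold is then given as at least that size. This allows for background in that group, and not for a higher floor or for the spread between arrays. Signals alone are given for such genes where that size lay above the ratio of the mean signals or depended on 1 array.

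The Spdef +/+ arrays called 24589 to 24833 probe sets Present, and the Spdef -/- arrays called 23290 to 23370 Present. The difference of the group means was -1352 probe sets (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays allow). The 3' over 5' signal ratio of the Gapdh and beta-actin control probe sets was 1.62 ± 0.20 on the log2 scale in Spdef +/+ and 1.51 ± 0.25 in Spdef -/- (exact permutation test, two-sided, p = 0.5). Log2 signals of arrays within a group correlated at 0.98 to 0.99 across probe sets, and those of arrays between groups at 0.914 to 0.934. Of the pooled sex-linked transcripts, the mean log2 signal of 4 Y-linked genes was 7.68 ± 0.09 in Spdef +/+ and 6.76 ± 0.80 in Spdef -/- (exact permutation test, two-sided, p = 0.1). The Y-linked Eif2s3y had a signal of 57.9 on Spdef -/- replicate 3 and of 301 to 566 on the other arrays, while Xist, transcribed from the inactive X chromosome, read 6091 ± 745 and 5778 ± 1415 (exact permutation test, two-sided, p = 0.8). Of the 5 tested sex-linked genes, Ddx3y alone passed the limma test, lower in Spdef -/- (adjusted p = 0.03), and it missed the threshold without any 1 of the 3 Spdef +/+ replicates (adjusted p from 0.0503 to 0.0903). The sex-linked list did not pass the set test (adjusted p = 0.308).

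As sets, goblet cell secretory products were lower in Spdef -/- than in Spdef +/+, although 1 member rose, and genes of the cornified envelope, of neutrophils, of cytokines and chemokines and of the cell cycle were higher. None of these sets passed with an estimated correlation (adjusted p = 0.581 for goblet cell products, 0.317 for the cornified envelope, 0.581 for neutrophils, 0.581 for cytokines and chemokines and 0.445 for the cell cycle). The targeted Spdef (probe set 1450220_a_at) had signals of 801, 689 and 587 on the Spdef +/+ arrays, and of 1, 3.62 and 2.94 with Absent calls on the Spdef -/- arrays. That is at least 248-fold lower by the rule above (adjusted p = 0.000152). The size depends on the floor. The log2 difference of -8.29 became -5.42 with a floor of 16 and -4.38 with a pseudocount of 32. Muc5ac, the main gel-forming mucin of conjunctival goblet cells, had a signal of 16558 ± 848 in Spdef +/+ and 14.5 ± 7.86, with Absent calls, in Spdef -/- (adjusted p = 3.88e-05). Among 11899 genes tested, 1878 were higher and 2850 lower in Spdef -/- (limma, adjusted p under 0.05).

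Beside Spdef and Muc5ac, the genes with the largest falls held other secretory genes. The gel-forming mucin Muc5b was at least 419.6-fold lower, and Ern2, an endoplasmic reticulum stress sensor of mucous cells, at least 127-fold. The secretoglobin gene Scgb1b2 fell from 8716 ± 1678 to 39.98 ± 8.90, Lman1l from 1024 ± 76.1 to 10.5 ± 6.60, and Frzb, a secreted Wnt antagonist, from 595 ± 59.0 to 5.26 ± 1.30. Ptprn2 fell from 270.3 ± 39.95 to 6.05 ± 6.01, and Foxa3, a forkhead transcription factor of goblet cells, from 619.9 ± 76.4 to 11.2 ± 4.96. Chad, Present on 1 Spdef -/- array, was 49.1-fold lower. Of 9 tested goblet cell secretory products 6 fell and 1 rose, and with p adjusted over the list alone 7 fell and 1 rose. The trefoil peptide gene Tff1 fell from 6871 ± 514 to 191 ± 30.1 (36.3-fold), and the disulfide isomerase gene Agr2, needed for mucin folding, fell 3.30-fold. The member that rose was Dmbt1, 6.92-fold higher. This list was lower as a set (adjusted p = 0.00322), and had an adjusted p = 0.581 with an estimated correlation, over alternatives with adjusted p from 5.05e-29 to 0.581. Without a filter on dim probe sets it missed the threshold (adjusted p = 0.0809). Of 10 tested secretory lineage regulators 5 fell and 1 rose, a list that did not pass the set test (adjusted p = 0.0902), and passed it without Spdef -/- replicate 1 (adjusted p = 0.029), under quantile normalization (adjusted p = 0.0454), with a floor of 16 (adjusted p = 0.0341), with a pseudocount of 32 (adjusted p = 0.0357), with arrays centred on bacterial controls (adjusted p = 1.05e-27) and by fry (adjusted p = 0.000686), over alternatives with adjusted p from 1.05e-27 to 0.581. Creb3l1, an activator of secretory pathway genes and Present on 1 Spdef -/- array, fell 8.36-fold. Klf4, which promotes differentiation of surface epithelia, was the member that rose (1.30-fold). Xbp1, with signals of 5103 ± 444 and 5656 ± 573, was not called. On Spdef -/- replicate 2 Lman1l had 3.27, against 16.2 and 12.1 on the other Spdef -/- arrays, and Ptprn2 had 12.95, against 1.95 and 3.24. Ptprn2 was not called, with a log2 difference of 0.04, when probe sets were not filtered by detection, because a brighter probe set, Absent on each array, then stood for it. Dmbt1 and Klf4 lie outside the naming rule and, like Xbp1, were chosen after their values were seen.

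**Figure D1:**
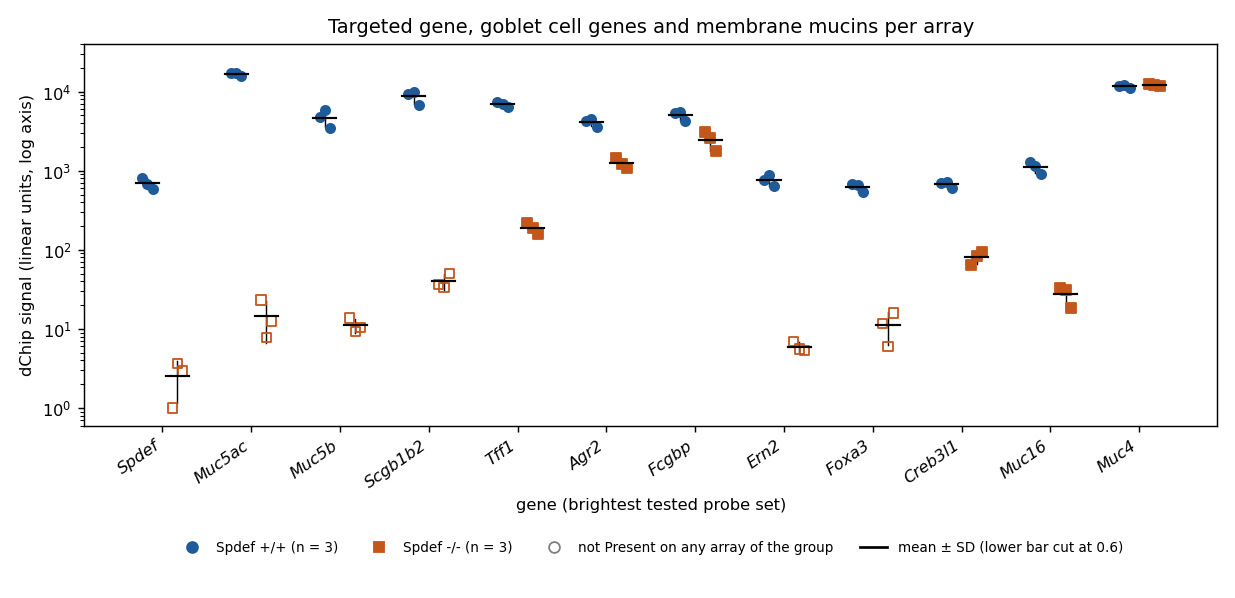
Signal of each array (dChip units, log axis) for Spdef, goblet cell genes and membrane mucins in Spdef +/+ (circles) and Spdef -/- (squares), with open symbols where no array of the group called the gene Present and bars for the mean ± SD of 3 arrays. Muc5ac had a mean of 16558 in Spdef +/+ and 14.5 in Spdef -/-, while Muc4 had 11673 and 12052.

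Enzymes that build mucin-type O-glycans moved both ways. Of 17 tested, 8 fell and 5 rose, and the list did not pass the set test (adjusted p = 0.404). Gcnt3, which branches mucin glycans, was at least 15.4-fold lower, and Galnt6 and Galnt5, which start O-glycosylation, fell from 362 ± 84.7 to 24.7 ± 6.69 and from 181 ± 19.1 to 37.3 ± 4.99. B3galt5, a galactosyltransferase, rose from 6.51 ± 3.45 to 456 ± 116. Of 6 tested membrane mucin and glycocalyx genes, 2 fell. Muc16, the large membrane mucin of the ocular surface and Present on 1 Spdef -/- array, fell from 1118 ± 188 to 27.3 ± 7.86 (41.9-fold), and Muc1 fell 1.36-fold. Muc4 was not called, at 11673 ± 556 and 12052 ± 430.0. This list had a positive median, a negative mean and a test direction of lower (adjusted p = 0.619). Of 11 tested ion and water transport genes 6 fell and 3 rose (set test adjusted p = 0.629). The anion exchanger gene Slc26a4, Present on 1 Spdef +/+ array, rose 58.9-fold, whereas the calcium-activated chloride channel gene Ano1 fell 4.56-fold, Kcne3 5.73-fold and Kcnq1 3.62-fold. The call of Muc1 held without Spdef -/- replicate 1 and was lost without any 1 of the other 5 arrays (adjusted p from 0.059 to 0.107).

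Of 11 tested genes of the cornified envelope, the cross-linked protein shell of stratified epithelial cells, 8 rose and none fell over the 11899 genes tested, and with p adjusted over the list alone 11 rose. Of the small proline-rich genes, Sprr2a1 went from 169 ± 63.2 to 11450.0 ± 2059 (70.1-fold), Sprr1a from 66.7 ± 9.18 to 4087 ± 1174 (60.1-fold), and Sprr2f, Present on 1 Spdef +/+ array, from 19.3 ± 9.09 to 2451 ± 614 (135-fold). Sprr2h was at least 29.4-fold higher. The list was higher as a set (adjusted p = 1.77e-07), and had an adjusted p = 0.317 with an estimated correlation, over alternatives with adjusted p from 2.01e-49 to 0.317. Of 7 tested epidermal genes 4 rose and 1 fell, and with p adjusted over the list alone 4 rose and 2 fell (set test adjusted p = 0.308). Calm4 was at least 4.23-fold higher, Krtdap rose from 8.76 ± 8.32 to 73.1 ± 29.2, and Krt1, a keratin of the upper epidermis, fell 1.88-fold. Krtdap had signals of 6.01, 2.16 and 18.1 on the Spdef +/+ arrays, and it passed without any 1 array. Of 6 tested keratins of conjunctiva and simple epithelia 3 rose and 1 fell, and with p adjusted over the list alone 3 rose and 2 fell (set test adjusted p = 0.462). Krt13, a keratin of stratified mucosa, rose from 5245 ± 643 to 10969 ± 1890.0 (2.08-fold) and Krt4, its partner, rose 1.38-fold, while Krt18, a keratin of simple epithelia and goblet cells, fell from 6271 ± 750.1 to 2089 ± 193. Of 10 tested basal cell genes 2 rose and 4 fell (set test adjusted p = 0.904). Krt14, a basal keratin, rose 1.57-fold, and the hemidesmosome and basement membrane genes Col17a1 and Lamb3 fell 1.34-fold and 1.29-fold. None of the 6 tested corneal epithelial genes passed limma (set test adjusted p = 0.275). Krt12, the keratin of corneal epithelium, had 2788 ± 2287 and 813 ± 578 with adjusted p = 0.103. Of 17 tested junction genes 6 rose and 5 fell, with a positive median, a negative mean and a test direction of higher (adjusted p = 0.445). Cldn8 and Cldn10 fell 1.90-fold and 2.53-fold, and the desmosomal Pkp3 rose 1.39-fold.

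**Figure D2:**
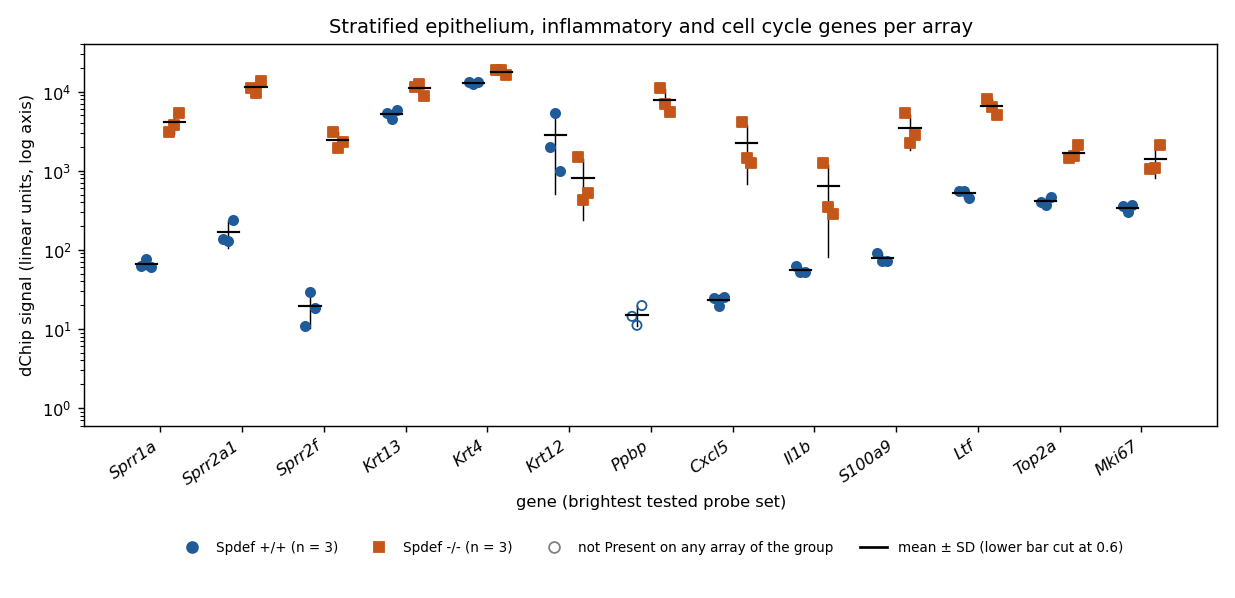
Signal of each array (dChip units, log axis) for genes of stratified epithelium, inflammation and the cell cycle in Spdef +/+ (circles) and Spdef -/- (squares), with open symbols where no array of the group called the gene Present and bars for the mean ± SD of 3 arrays. Sprr1a had a mean of 66.7 in Spdef +/+ and 4087 in Spdef -/-, while Krt12 had overlapping arrays.

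The platelet chemokine gene Ppbp went from 15.1 ± 4.34 to 7775 ± 2866, at least 508-fold higher. The neutrophil-attracting chemokine genes Cxcl3, Present on 1 Spdef +/+ array, and Cxcl5, Present on 2, rose 111-fold and 85.0-fold. Of 16 tested cytokines and chemokines 12 rose and 2 fell. Csf3, the growth factor of granulocytes, rose 12.8-fold, the alarmin Il33 3.97-fold, Cxcl1 3.50-fold, and Il1b, at 55.9 ± 5.47 and 633 ± 551, 8.97-fold. The list was higher as a set (adjusted p = 0.000307), and had an adjusted p = 0.581 with an estimated correlation, over alternatives with adjusted p from 3.9e-22 to 0.581. Tnf was not among the tested genes. Of 5 tested neutrophil genes 4 rose, and with p adjusted over the list alone 5 rose. S100a9 rose 41.3-fold, its partner S100a8 15.8-fold, and Csf3r, the receptor of Csf3, at least 19.5-fold. This list was higher as a set (adjusted p = 0.00158), and had an adjusted p = 0.581 with an estimated correlation, over alternatives with adjusted p from 1.48e-19 to 0.581. The genes S100a8 and S100a9 also stand in the list of antimicrobial and epithelial defence, of whose 13 tested members 5 rose and 3 fell (set test adjusted p = 0.166). Ltf, an iron-binding protein of tears, rose from 521 ± 65.1 to 6532 ± 1549 (12.4-fold), and the antimicrobial lectin gene Reg3g fell from 326 ± 115 to 28.9 ± 11.6. The acute phase gene Saa3, Present on 1 Spdef +/+ array, rose 63.8-fold. Without 1 array the fold of Saa3 was 123 (Spdef +/+ replicate 2), 34.8 (Spdef +/+ replicate 3) or 42.5 (Spdef -/- replicate 3), and that of Il1b was 5.63 without Spdef -/- replicate 1.

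Complement genes rose in 7 of 9 tested members and fell in 1, and with p adjusted over the list alone 7 rose and 2 fell. C3, the central complement component, rose 5.81-fold, and Cd55, an inhibitor of complement, fell 5.49-fold. This list was higher as a set (adjusted p = 0.0421), and had an adjusted p = 0.581 with an estimated correlation, over alternatives with adjusted p from 0.0253 to 0.581. It missed the threshold without Spdef -/- replicate 1 (adjusted p = 0.0501) or replicate 3 (adjusted p = 0.0813), without the filter (adjusted p = 0.0709), under quantile normalization (adjusted p = 0.0566), with arrays centred on their medians (adjusted p = 0.0833) and with probe sets of several gene IDs left unnamed (adjusted p = 0.101). Of 7 tested type 2 response genes 5 rose and 1 fell. Chil4, a chitinase-like protein, rose from 4.92 ± 0.869 to 938 ± 1253, the lipoxygenase gene Alox15 rose 12.6-fold, and Arg1 rose 1.89-fold. The member that fell was Retnla (3.32-fold), chosen after its values were seen, Present on 2 Spdef -/- arrays, which missed the threshold without Spdef +/+ replicate 2 (adjusted p = 0.0643) or replicate 3 (adjusted p = 0.0755). The list was higher as a set (adjusted p = 0.0255), and had an adjusted p = 0.444 with an estimated correlation, over alternatives with adjusted p from 3.59e-08 to 0.444. It missed the threshold when genes were filtered by mean signal (adjusted p = 0.0796) and with arrays centred on their medians (adjusted p = 0.0531). The signal of Chil4 was 2385 on Spdef -/- replicate 3 and 265 and 165 on the other Spdef -/- arrays, and the fold of Alox15 was 19.7 without Spdef +/+ replicate 3.

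Of 5 tested B and plasma cell genes 3 rose. The B cell receptor subunit gene Cd79b rose from 65.6 ± 4.30 to 197 ± 17.8, and Ms4a1 and Iglv1, each Present on 1 Spdef +/+ array, rose 3.06-fold and 4.84-fold. The list was higher as a set (adjusted p = 0.00229), and had an adjusted p = 0.444 with an estimated correlation, over alternatives with adjusted p from 1.61e-06 to 0.444. Glycam1, a mucin-like ligand made by the endothelium of lymph node venules, was at least 71.0-fold higher, at 1.70 ± 0.766 and 218 ± 42.4. Of 10 tested T and NK cell genes 5 rose and 2 fell, and with p adjusted over the list alone 6 rose and 2 fell. Cd3d rose from 28.1 ± 2.93 to 63.2 ± 4.10, and the granzyme gene Gzma, Present on 1 Spdef -/- array, fell 3.12-fold. This list did not pass the set test (adjusted p = 0.0585), and passed it without Spdef +/+ replicate 2 (adjusted p = 0.0476) or without Spdef -/- replicate 2 (adjusted p = 0.0404), over alternatives with adjusted p from 0.0158 to 0.502. Of 17 tested macrophage and dendritic cell genes 2 rose and 1 fell, and with p adjusted over the list alone none rose and 1 fell (set test adjusted p = 0.141). The scavenger receptor gene Cd163 fell 1.90-fold. The list passed the set test without Spdef +/+ replicate 2 (adjusted p = 0.017) or without Spdef -/- replicate 2 (adjusted p = 0.0277), over alternatives with adjusted p from 0.017 to 0.804. In mast cells and eosinophils 2 members were tested, too few for the set test, and both fell, the mast cell protease gene Cma1 at least 3.15-fold and Kit 1.43-fold, the latter not without Spdef +/+ replicate 1 (adjusted p = 0.074) or replicate 3 (adjusted p = 0.0672).

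Of 8 tested genes of class II antigen presentation 6 rose, and with p adjusted over the list alone 6 rose and 1 fell. H2-Ab1 rose from 2945 ± 238 to 4319 ± 452 (1.46-fold) and H2-DMa rose 1.45-fold. The list was higher as a set (adjusted p = 0.0396), and had an adjusted p = 0.581 with an estimated correlation, over alternatives with adjusted p from 0.0057 to 0.581. It missed the threshold without Spdef +/+ replicate 3 (adjusted p = 0.061), Spdef -/- replicate 1 (adjusted p = 0.0501) or Spdef -/- replicate 3 (adjusted p = 0.115), with arrays centred on their medians (adjusted p = 0.0531) or on bacterial controls (adjusted p = 0.261), and with array weights (adjusted p = 0.0816). Of 9 tested genes of class I antigen presentation 4 fell and none rose by limma (set test adjusted p = 0.28), among them the immunoproteasome genes Psmb10, 1.39-fold lower, and Psmb9, 1.48-fold lower. The immunoproteasome gene Psmb8 fell 1.35-fold by its brightest probe set, and had a log2 difference of 0.01 in the mean of its probe sets. Of 19 tested interferon response genes 6 fell and none rose by limma (set test adjusted p = 0.111). Mx1 and Ifi44, both induced by interferon, fell 2.78-fold and 2.55-fold. The interferon list passed the set test without Spdef +/+ replicate 3 (adjusted p = 0.0476) and with array weights (adjusted p = 0.0493), over alternatives with adjusted p from 0.0375 to 0.581.

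The cell cycle list moved as a whole, with 21 of 21 tested genes higher. Top2a, the DNA topoisomerase of dividing cells, rose from 414 ± 53.3 to 1697 ± 342 (4.07-fold), Rrm2 rose 4.69-fold, Cdk1 4.26-fold and Ccnb1 3.26-fold. As a set these genes were higher (adjusted p = 4.98e-13), and had an adjusted p = 0.445 with an estimated correlation, over alternatives with adjusted p from 3.02e-24 to 0.445. Of 13 tested immediate early genes, which respond to growth factors and stress within minutes, 7 rose, and with p adjusted over the list alone 8 rose. Egr3, Present on 1 Spdef +/+ array, rose 3.38-fold, Fos 2.59-fold and Egr1 2.22-fold. This list was higher as a set (adjusted p = 4.1e-05), and had an adjusted p = 0.279 with an estimated correlation, over alternatives with adjusted p from 1.25e-05 to 0.279. Of 25 tested genes of protein folding and export in the endoplasmic reticulum 13 rose and 1 fell, and with p adjusted over the list alone 14 rose and 1 fell. Sec61b, a subunit of the protein-conducting channel, rose 1.54-fold and Manf 1.45-fold, while Kdelr3, a retrieval receptor of secretory cells, fell 3.95-fold. As a set the list was higher (adjusted p = 0.00158), and had an adjusted p = 0.581 with an estimated correlation, over alternatives with adjusted p from 0.000152 to 0.581. It missed the threshold with arrays centred on bacterial controls (adjusted p = 0.0971). Of 17 tested Notch and Wnt pathway genes 5 fell and none rose by limma (set test adjusted p = 0.141). Dkk3, a secreted protein of the Dickkopf family, fell 2.12-fold, and the Notch ligand gene Jag1 fell 1.54-fold. Of 11 tested oxidative stress genes 1 rose and 3 fell, with a negative median and mean and a test direction of higher that turned under quantile normalization (adjusted p = 0.941). Catalase, Cat, fell 1.77-fold.

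Of 14 tested fibroblast and stroma genes 9 fell and none rose by limma, and with p adjusted over the list alone 11 fell. Sparc fell from 5505 ± 1354 to 2419 ± 127 (2.23-fold), the collagen gene Col1a2 from 10909 ± 2198 to 5629 ± 527 (1.92-fold), and Col6a1 and Col6a2 2.21-fold and 2.13-fold. The list was lower as a set (adjusted p = 0.0057), and had an adjusted p = 0.581 with an estimated correlation, over alternatives with adjusted p from 0.000154 to 0.581. With array weights it missed the threshold (adjusted p = 0.0521). Whether less stroma was captured in Spdef -/- or its genes were expressed less was not tested. Of 10 tested matrix proteases and inhibitors 6 rose and 3 fell (set test adjusted p = 0.18). Serpinb2, a plasminogen activator inhibitor, rose 23.5-fold, and the gelatinase gene Mmp2 and its inhibitor gene Timp2 fell 2.36-fold and 1.86-fold. Of 10 tested genes of endothelium and pericytes 1 rose and 2 fell, with a negative median and mean and a test direction of higher (adjusted p = 0.619). Vwf, the endothelial clotting factor gene, rose 2.08-fold and Cldn5 fell 2.02-fold. Of 4 tested skeletal muscle genes 1 rose, Tnni2 (1.87-fold), with a negative median and mean and a test direction of higher that turned with arrays centred on bacterial controls (adjusted p = 0.57). In red blood cells 1 gene was tested, too few for the set test, and Hba-a1 was not called at 3491 ± 1333 and 2372 ± 1703. Of 3 tested melanocyte genes 1 fell, Dct (2.27-fold), Present on 2 Spdef +/+ arrays and 1 Spdef -/- array, and with p adjusted over the list alone none passed (set test adjusted p = 0.602). The call of Dct held without Spdef +/+ replicate 3 and was lost without any 1 of the other 5 arrays (adjusted p from 0.0851 to 0.131). Of 7 tested genes of the meibomian and sebaceous glands 1 rose and 1 fell, with a negative median and mean and a test direction of higher (adjusted p = 0.864). Fabp5, a fatty acid carrier, rose 4.48-fold and Mgst1 fell 1.37-fold. Of 3 tested genes of lacrimal acini Ltf rose, the salivary-type amylase gene Amy1, Present on 1 Spdef -/- array, fell 6.99-fold, and the water channel gene Aqp5 was not called (set test adjusted p = 0.582).

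**Figure D3:**
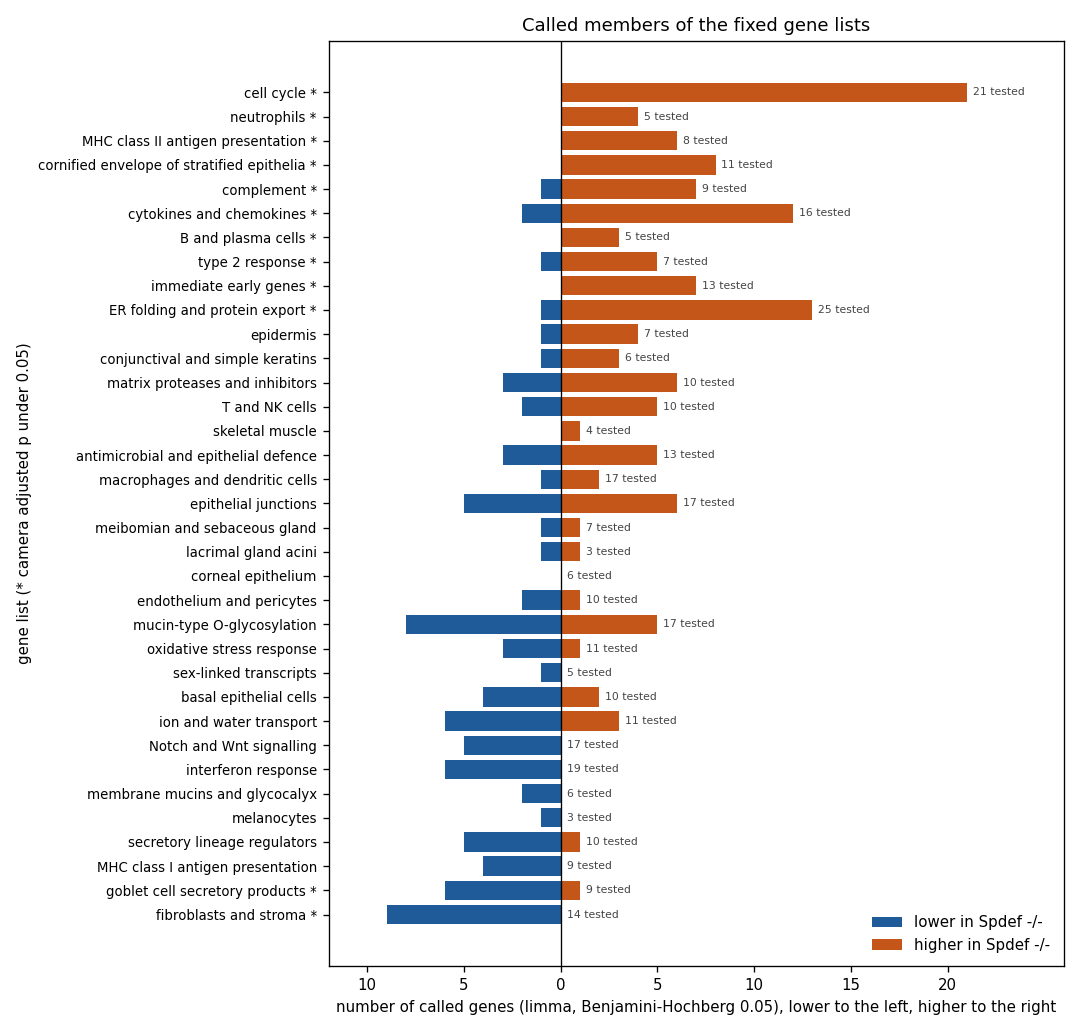
Number of genes called higher (right) and lower (left) in Spdef -/- (limma, 3 against 3 arrays) for each of the 35 tested lists, with the number tested at the end of each bar and an asterisk where the set test passed. The cell cycle list had 21 of 21 tested genes higher and the fibroblast and stroma list 9 of 14 lower.

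The 4728 called genes were 39.7% of those tested. Of the higher genes 494 differed at least 2-fold and 30 at least 10-fold, and of the lower genes 587 and 33. The groups did not overlap in 6582 genes (55.3%), where chance would give 10%. The median log2 difference of the tested genes was -0.06, and it was -0.17 with arrays centred on the bacterial hybridisation controls, whose mean log2 signal was 11.58 on Spdef -/- replicate 3 and 10.80 to 11.19 on the other arrays. Of the 35 tested lists 12 passed the set test, 10 higher and 2 lower. With an estimated correlation none of the 12 passed after adjustment, and 3 had an unadjusted p under 0.05, the cornified envelope (p = 0.0181), B and plasma cells (p = 0.0386) and immediate early genes (p = 0.00798), while fry called 22 lists. Where no count adjusted over the list alone is given, it equalled the count over the tested genes.

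Centring the arrays on the bacterial controls, an alternative chosen after the data were seen, left 1593 genes past the threshold, 523 higher and 1070 lower. It ended the calls of Muc1, Krt4, Krt14, Col17a1, Lamb3, Pkp3, H2-Ab1, H2-DMa, Psmb8, Psmb9, Psmb10, Arg1, Sec61b, Manf, Jag1, Mgst1, Kit and Tnni2 (adjusted p from 0.0822 for Arg1 to 0.597 for Krt4), whose adjusted p over the alternatives ran from 2.74e-05 for Krt14 to 0.983 for Psmb8, and of Klf4 (adjusted p = 0.728, the highest over the alternatives run for it, of which the lowest was 0.00441). It brought Krt12 (adjusted p = 1.38e-06) and Hba-a1 (adjusted p = 0.037) past the threshold. It also brought past the threshold 5 lists that had not passed, secretory lineage regulators, antimicrobial and epithelial defence (adjusted p = 1.62e-08, from 1.62e-08 to 0.761 over alternatives), matrix proteases and inhibitors (adjusted p = 0.0145, from 0.0145 to 0.581), membrane mucins and glycocalyx (adjusted p = 0.015, from 0.015 to 0.907) and epidermis (adjusted p = 0.03, from 0.03 to 0.914). Under this centring the adjusted p of the named genes followed the size of the log2 difference. That size was 0.81 for Arg1, -0.92 for Hba-a1 and -1.78 for Krt12. A gene's own spread between arrays, wide in Krt12 and Hba-a1, had little weight. The calls and small p values gained by this centring are therefore not read as support. They also set the low end of some ranges given over alternatives, such as that of secretory lineage regulators. Other alternatives ended the calls of Dct, Ddx3y, Kit, Muc1 and Tnni2 without the filter (adjusted p from 0.0545 for Tnni2 to 0.113 for Dct), of Dct and Muc1 with arrays centred on their medians (adjusted p = 0.056 and 0.0555), and of Dct, Ddx3y, Kit and Psmb8 in the mean of a gene's probe sets (adjusted p from 0.0503 for Dct to 0.983 for Psmb8). Fry, which asks whether a list moved one way and does not compare it with other genes, ended the calls of class II antigen presentation, of complement and of protein folding and export (adjusted p from 0.0851 to 0.0857). It called 13 lists that had not passed, secretory regulators, O-glycosylation, membrane mucins, corneal epithelium, epidermis, lacrimal acini, T and NK cells, class I antigen presentation, interferon response, antimicrobial defence, ion transport, Notch and Wnt signalling and sex-linked transcripts (adjusted p from 0.000686 to 0.0496).

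The authors' deposited table lists 153 probe sets, 43 higher and 110 lower in Spdef -/-, that met a fold bound over 3, a difference over 20 and a p of at most 0.01. Of the 142 probe sets of the authors' deposited table that were tested here, 142 passed limma in the direction of that table, 41 higher and 101 lower. The other 11 were Present on fewer than 3 arrays and were not tested. Since the authors' deposited table was drawn from the same arrays, its overlap is not independent evidence. Of 24533 probe sets tested for this overlap, 7931 passed limma, of which 654 differed at least 3-fold.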

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

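The values in this part were looked for after the data were seen. Of 2806 tested probe sets without a gene symbol, a group that took in those matching several genes, 165 were higher and 513 lower in Spdef -/- (limma). Among those that rose, probe set 1456539_at had a mean signal of 6.42 in Spdef +/+ and 693 in Spdef -/-, and 1425451_s_at had 9.25 and 1316, both with no Present call in Spdef +/+. Among those that fell, 1440409_at had 675 and 22.7, and 1446657_at had 65.2 and 3.99. The array's control probe set for the B2 repeat, a short interspersed element, had a signal of 1082 on Spdef -/- replicate 3 and of 406 to 528 on the other arrays. The control for the B1 repeat had 4703 on that array and 2883 to 3316 on the others.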

How the results depend on the processing

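Centring on bacterial controls and leaving probe sets of several IDs unnamed were chosen after the data were seen. Against 4728 genes, 2850 of them lower, the count was 3127 to 4559 without 1 array (1277 to 1825 higher, 1850 to 2734 lower), 1593 with arrays centred on bacterial controls (523 higher, 1070 lower), 7269 for probe sets singly (2908 higher, 4361 lower), 427 at 3-fold and an unadjusted limma p under 0.01 (225 higher, 202 lower), and 305 at 3-fold with the methods' t-test on linear signals (135 higher, 170 lower). The other settings that kept the adjusted threshold of limma gave 3470 (no filter) to 5879 (array weights). The replicate number as a block gave 3673 (1473 higher, 2200 lower). It ended the calls of Muc1, Dct, Kit and Ddx3y (adjusted p = 0.0549, 0.0695, 0.0521 and 0.0698) among its 14, and brought T and NK cells past the threshold (adjusted p = 0.0352, from 0.0158 to 0.502 over alternatives). Further, deviations from the group mean correlated within those pairs of arrays at -0.013, -0.090 and -0.084. The model without pairing had been fixed before the data were examined. The percentage of calls that were higher was 39.7, and 46.4 under quantile normalization and 49.5 with arrays centred on their medians. Lists past the threshold numbered 12, 10 to 14 without 1 array, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 22 with fry. The log2 difference of Spdef was -8.65 to -7.72 without 1 array, -5.42 with a floor of 16 and -4.38 with a pseudocount of 32. Spdef had no value under the filter on mean signal. Without 1 array, the difference in detected probe sets was -1404 to -1282, that in the 3' over 5' ratio -0.25 to -0.01, that of the Y-linked mean -1.27 to -0.48, and 140 to 142 probe sets of the authors' deposited table were past the threshold. Uty alone differed by -0.33 and Xist alone by -0.10. A pair of genes changed sign. Ptprn2 had 0.0444 without a filter and 0.0444 under the filter on mean signal, where a brighter probe set, Absent on each array, was chosen, and Psmb8 had 0.0128 in the mean of its probe sets, where the cause was not tested. Of the 131 named genes, the bacterial centring ended 43 calls and no filter 17 beside that of Ptprn2, and the cause was not tested. The block ended 14 and left the log2 differences of these genes unchanged, so the precision of the test changed and not the size. Array signal over background limits genes Absent in a group to bounds, and these depend on the floor set under the signals.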

Other observations

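The tests in this part were chosen after the results were seen, except the count of splits and the test of the neighbours of Spdef. Tested genes were grouped by the stem of their symbol into 197 families of at least 8 members, and 13 of 394 tests (Fisher's exact test against the other tested genes, one-sided, adjusted over the 394) passed. Of these, 4 also passed under 3 other scalings and without each of the 6 arrays in turn. Among the 3 scalings was the centring on bacterial controls, whose gained calls and small p values are not read as support. Genes with the stem Tnfrsf missed the threshold under that centring alone (adjusted p = 0.0519). Genes with the stem Il, among them interleukins and their receptors, were higher in 22 of 39 (adjusted p = 2.66e-06), with 1 of the 39 lower. Minichromosome maintenance genes (Mcm), which license DNA replication, were higher in 7 of 10 (adjusted p = 0.0122). Collagen genes (Col) were lower in 16 of 22 (adjusted p = 0.000243) and cytochrome P450 genes (Cyp) in 15 of 27 (adjusted p = 0.0178), with 4 of the 27 higher. With arrays centred on bacterial controls these counts were 11 for Il, 6 for Mcm, 13 for Col and 11 for Cyp. Among the last, Cyp2b10 fell 15.9-fold and Cyp4f15 5.24-fold. Fisher's test treats genes as independent, and genes of a family can move together, so its p does not measure the spread between arrays. Members of the Il, Mcm and Col families also stand in the fixed lists of cytokines, cell cycle and stroma.

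Single genes picked after their values were seen stand for no group. Aldh1a1, which makes retinoic acid, fell 13.4-fold, whereas Aldh1a3, which does so too, rose 3.52-fold and Crabp2, a carrier of retinoic acid, rose 7.23-fold. Krt16 and Krt17, keratins of wounded or hyperproliferative epidermis, rose 32.5-fold and 4.87-fold, the first Present on 1 Spdef +/+ array. In a list of hyperproliferative keratinocytes, drawn up after such genes were seen to rise, 10 of 12 tested genes were higher, and 6 with arrays centred on bacterial controls. In lists of retina photoreceptors and of germinal centre cells 1 of 4 tested genes was lower and 1 of 4 higher, and 0 in either with that centring.

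The 6 arrays have 10 splits into 3 and 3, too few for a share under 0.05. Genes past the limma threshold numbered 4728 in the real split, which was 1 of 10 with as many, and at most 0 in the others, where up to 377 genes had an unadjusted p under 0.05 against 5915 in the real split.

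The cell cycle genes rose in 21 of 21. If a lower share of goblet cell RNA had raised the rest, basal and cell cycle genes would have moved alike. A rise shared by all other genes could be scaled out between arrays, so the lists are compared with each other. Basal genes had a median log2 difference of -0.16 (SD 0.38), with 2 of 10 higher and 4 lower, but the cell cycle had 1.81 (SD 0.43). At least 20 of the 21 were called without any 1 array, which argues against 1 array carrying the rise. Dividing lymphocytes may contribute, since the B and plasma cell list had a median of 1.61, with its brightest gene, Jchain, at 211 ± 194 and 649 ± 488 and not called, and that stays open.

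In a list of lymphoid tissue and B cell follicle genes, drawn up after such genes were seen to rise and with 3 members in the fixed lists, 18 of 19 tested genes were higher. Deeper capture that took in more stroma in Spdef -/- would have raised stroma genes, whose median log2 difference was -0.93 (SD 0.40). That cannot decide whether more lymphoid tissue was captured, since stroma genes need not rise with it. Without 1 array the fewest called was 15, without Spdef +/+ replicate 3 or Spdef -/- replicate 3. Of the brightest members, Cd74 had 4754 ± 268 and 6099 ± 760.4 and the follicle chemokine gene Cxcl13 had 107 ± 20.8 and 1015 ± 228. Other explanations were not tested and stay open.

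Of 12 tested lens genes, 0 of which stand in the fixed lists, 8 were lower in Spdef -/-, and the count was 2 without Spdef +/+ replicate 1, 3 without Spdef +/+ replicate 3, 4 without Spdef -/- replicate 1 or 2 and 11 without Spdef -/- replicate 3. Crygs had signals of 2004, 668.5 and 2222 in Spdef +/+ and of 316.5, 126 and 501.7 in Spdef -/-. In 12 of the 12, Spdef +/+ replicate 2 had the lowest signal of its group, as it did in 33.9% of the tested genes, and its log2 signal lay under the mean of the other 2 by a median of -1.44 (SD 0.51). Lens genes can move together between arrays, so the 12 are not separate observations and the share of all tested genes is no close reference. Lens RNA carried into the samples in unequal amounts is a candidate explanation. The count cannot decide it, since a shared difference in expression between samples would give the same count. A difference by genotype was not tested apart from it.

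Of the 100 tested genes nearest to Spdef on its chromosome, 42 were called, 19 higher and 23 lower, where windows of 100 neighbouring genes had a median of 39 and a 95th percentile of 47 (Fisher's exact test, two-sided, p = 0.682). This count leaves open whether donor DNA around the targeted gene changes single neighbours.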
